A study of Homo sapiens with 6 samples.

How the data were processed

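Cells of 3 NCI-N87 xenografts were sorted into a PG1hi and a PG1lo fraction, and 1 library per fraction and tumor was made with the SMART-Seq v4 and Nextera XT kits, per the labels' protocols. The names PG1, AF647, T-AP1 and PTA (the name of the injected agent in the treatment label) are used as given. The submitters' processing notes name STAR 2.6.0c, edgeR and the builds hg19 and GRCh37, with no role for each. The counting tool and the gene annotation are not given in the sources used here.

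The deposited table of the series holds estimated counts, which need not be whole, in 72212 rows; as the values show, several rows can share 1 Entrez Gene ID, up to 116. In the deposited file of each library the authors gave 1 scaled signal per gene. For genes with a single row, this signal is the estimated count times 1 factor per library within a tolerance of 0.1% in 90.7% to 91.4% of genes. Multiplying back gave whole numbers, within 0.01, for 63.6% to 65.0% of values, so whole reads were not recovered. The test planned for raw counts was therefore run on rounded estimates.

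Rows were summed per Entrez ID to 28006 genes and rounded to whole numbers. Symbols came from the RefSeq gene table by ID, for 27940 of the 28006 genes. The 383 rows that name no gene held 2.5% to 4.48% of the counts and were left out of library sizes and tests. No mitochondrially encoded gene had a row, so that list has 0 tested members, and 1 listed TGF-beta target was not analysed here. The reference annotation is of another build than the authors', so coordinates are not printed, and it served only for transcript length and GC content. The totals of 27544756 to 36178016 estimated counts per library set the precision, and PCR copies are not independent molecules, so counting error understates the error.

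The 2 groups were compared as PG1hi minus PG1lo with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. SE is the log2 change divided by the root of F. CPM are TMM-scaled. Fractions numbered alike come from the same tumor by their labels. Across 15077 genes, their deviations from the group means correlated at 0.365, 0.149 and 0.259 in tumors 1, 2 and 3 (genes are not independent replicates), against -0.267 to 0.0262 for fractions of different tumors. The tumor number therefore pairs the libraries, and the fit with the tumor number as a block is given beside the fit without it. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members, Benjamini-Hochberg over 35 lists), with camera with a correlation estimated per list, and with fry. Library properties were compared with a two-sided exact permutation test in Python 3.11.15 with scipy 1.17.1.

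Data were simulated for this comparison from the libraries' means, tumor effects and sizes, with the spread estimated in the fit with block. They covered 14825 genes in 3 draws with 200 changed genes each. The fit without block recovered 26.3% of changes of 0.5 and 87.7% of changes of 1 on the log2 scale. The paired fit recovered 85.7% and 99.7%, and 8.55% of its calls were false. Because the simulated data hold tumor effects, the gain of the paired fit was built in and does not decide between the fits. With no gene changed the fits called 0 and 2 genes.

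The lists, the rule for named genes and the alternatives, except those named last, were fixed before the data were examined. Named genes were those past the threshold without block, with a mean of at least 5 CPM, the same direction in all 3 tumors and a symbol that is not a clone or open-reading-frame name: the 12 largest changes each way. Because under 5 genes passed, the 6 smallest unadjusted p-values each way were added, and they are given as not past the threshold. Up to 4 members with the smallest p were also chosen from each list in each fit, and not all of them are named below. A further 9 genes were named whatever their values: ERBB2, CAT, NQO1, HMOX1, GPX2, CA9, MKI67, VIM and CDH1. The use of the same rule in the paired fit was decided after the counts were seen. Of the genes past the threshold in the paired fit, 2 that belong to the lists are not reported here.

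The alternatives were the block, DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size alone, no filter, a filter of 5 CPM in 3 libraries, a test against a 1.5-fold change, ribosomal protein genes removed, and each library and each tumor left out. Alternatives in the paired fit, offsets for GC content and length (natural splines with 4 degrees of freedom; 96.4% of tested genes had both), and limma on log2(signal + 1) of the authors' scaled files were added after the data were seen.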

Results

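RNA was sequenced from cells of NCI-N87 xenografts that had been sorted by the fluorescence of PG1. NCI-N87 is a human gastric cancer cell line with amplified ERBB2, the gene of the receptor HER2. The cells, injected in 50% Matrigel, were grown under the skin of nude mice for 21 days. A probe named T-AP1 in the series text was given 12 h before the tumors were taken. Cells that excluded propidium iodide were sorted on PG1 and AF647. There were 2 groups of 3 libraries, PG1hi and PG1lo, and each of the 3 tumors gave 1 library to each group. Summed over named genes, the libraries held between 27544756 and 36178016 estimated counts. In PG1hi 18149 ± 222 genes were detected and in PG1lo 18071 ± 200 (SD, n = 3 each). The labels number the tumors and do not say whether each came from its own mouse.

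ERBB2 took 1.28% ± 0.07 of the counts in PG1hi and 1.27% ± 0.11 in PG1lo (SD, n = 3 each). The share of ribosomal RNA genes was 4.06% ± 0.59 in PG1hi and 3.54% ± 0.38 in PG1lo, and PG1hi was the higher library in 3 of 3 tumors (two-sided exact permutation test, p = 0.3). The share of ribosomal protein genes was 2.45% ± 0.17 in PG1hi and 2.23% ± 0.20 in PG1lo, again higher in PG1hi in 3 of 3 tumors (two-sided exact permutation test, p = 0.2). The smallest p that 3 libraries against 3 allow in this test is 0.1. Total counts gave p = 0.5 and detected genes p = 0.7 in the same exact test.

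The comparison asked which genes differ between cells with high and cells with low PG1 fluorescence. PG1hi cells carried more NKD1, an antagonist and target gene of Wnt signaling, at 99.2 ± 1.8 CPM against 56.0 ± 2.5 CPM in PG1lo (SD, n = 3 each). They carried less TGM2, tissue transglutaminase, at 85.6 ± 7.9 against 147 ± 6.8 CPM. They also carried less CYP4B1, a cytochrome P450 monooxygenase, at 13.3 ± 1.2 against 25.2 ± 1.7 CPM. On the log2 scale NKD1 rose by 0.82 ± 0.07 (SE), TGM2 fell by 0.78 ± 0.09 and CYP4B1 fell by 0.92 ± 0.11, each in 3 of 3 tumors. These were the 3 genes past the threshold among 15077 tested when tumors were not matched (edgeR quasi-likelihood test, adjusted p = 0.00835 for NKD1 and 0.0356 for both TGM2 and CYP4B1). With the tumor number as a block, 767 genes passed, 249 higher and 518 lower in PG1hi, and all 3 genes were among them. DESeq2 without the block called 118, of which 117 were tested here and all 117 were also called in the paired fit. In the fit without block, TGM2 and CYP4B1 lost their calls whichever of the 6 libraries was left out (edgeR, adjusted p between 0.0626 and 0.165 for both), with log2 changes from -0.82 to -0.70 for TGM2 and from -0.96 to -0.85 for CYP4B1. NKD1 lost its call without PG1hi replicate 2 (adjusted p = 0.104), PG1lo replicate 1 (0.0764) or PG1lo replicate 2 (0.096), and its log2 change stayed between 0.79 and 0.85. In the paired fit all 3 genes kept their calls without each tumor in turn.

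Most of the 767 differences were small. Their median size was 0.34 on the log2 scale, 137 exceeded a 1.5-fold change and 36 exceeded a 2-fold change. In all 3 tumors 765 went the same way, which follows largely from the choice, because the paired test picks genes with like differences in these tumors. Scaling by library size alone moved the split to 369 higher and 357 lower in the paired fit. In the whole set of tested genes 38.7% went the same way in all 3 tumors, where 25% would by chance.

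The growth factor gene FGF20 rose the furthest in PG1hi among genes past the threshold with a mean of at least 5 CPM in the paired fit. It was at 16.4 ± 2.9 CPM in PG1hi and 7.61 ± 1.3 CPM in PG1lo, a log2 change of 1.11 ± 0.14 (SE; edgeR with block, adjusted p = 0.000237). CA9, a carbonic anhydrase induced by hypoxia, rose by 0.97 ± 0.16. Its change without the block, 0.89, was 0.22 without PG1hi replicate 3, 0.55 without PG1lo replicate 1 and 1.80 without PG1lo replicate 3. In the paired fit CA9 was steadier, at 0.96, 0.85 and 1.11 without tumors 1, 2 and 3, and kept its call each time. VIL1, an actin-bundling protein of microvilli, rose by 0.88 ± 0.09. IL1R2, a decoy receptor for interleukin 1, rose by 0.96, CLRN3 by 0.84 and PNMT, the enzyme that makes adrenaline, by 0.77. TWIST1, a transcription factor of mesenchymal cells, rose by 0.76, the connexin gene GJA3 by 0.75 and the matrix glycoprotein gene TNC by 0.73. SERF1A rose by 1.08 and MIA-RAB4B by 0.85, but SERF1A has a near-identical copy and MIA-RAB4B overlaps its neighbors, so their counts are uncertain. Of these genes NKD1 alone passed without the block. CCL24 and MAN1A1, at log2 changes of 0.68 and 0.46, were among the 6 smallest p-values of the higher genes without the block (adjusted p = 0.118 and 0.181, edgeR).

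HOPX, a homeodomain protein without DNA binding of its own, fell the furthest in PG1hi among genes past the threshold with a mean of at least 5 CPM in the paired fit, from 66.0 ± 25.1 CPM in PG1lo to 30.5 ± 10.1 CPM in PG1hi (SD, n = 3 each). Its log2 change was -1.10 ± 0.07 (SE; edgeR with block, adjusted p = 7.6e-07). UPK2, a uroplakin of the urothelial surface, fell by 1.09 ± 0.14, and MAL, a proteolipid of apical transport, fell by 1.05 ± 0.10. KRT13, a keratin of stratified epithelia, went from 183 ± 41.1 to 93.0 ± 14.3 CPM and fell by 0.96 ± 0.06. The copper transporter gene SLC31A2 fell by 1.04, TTYH1 by 0.89, ANKFN1 by 0.89, MDFIC by 0.87, the adhesion gene NCAM1 by 0.83, the gasdermin gene GSDMC by 0.82 and the adhesion gene ICAM1 by 0.82. ALPP and ALPG, the placental and germ cell alkaline phosphatases, fell by 0.70 and 0.66 in the paired fit, and their counts are uncertain because the 2 genes are near-identical. The chemokine gene CXCL8 fell by 0.76. Without the block, adjusted p was 0.061 for CXCL8 and ALPP and 0.0711 for ALPG and ICAM1 (edgeR).

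**Figure D1:**
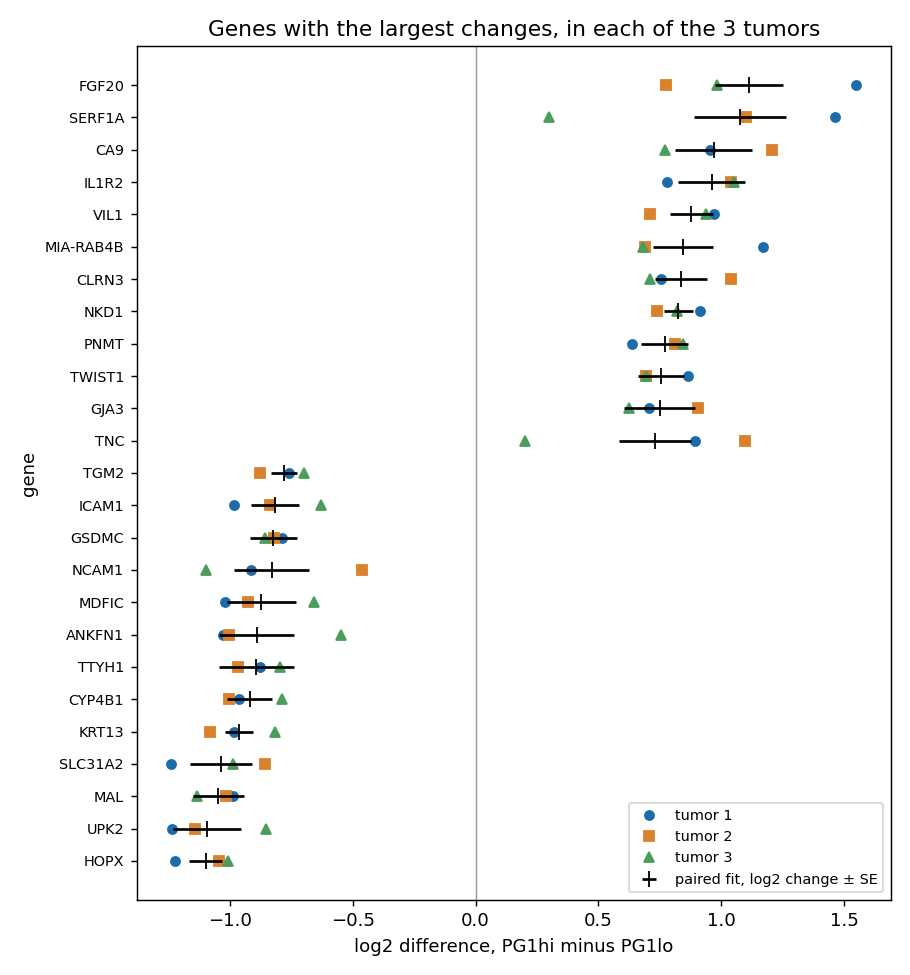
Log2 difference of PG1hi minus PG1lo within each of the 3 tumors (points) for the genes past the threshold without block and the 12 largest changes each way in the paired fit, chosen with a mean of at least 5 CPM and the same direction in all 3 tumors, with the log2 change ± SE of the paired fit (vertical mark and bar). All points of a plotted gene lie on 1 side of 0 by this choice; of the plotted genes FGF20 has the highest paired change at 1.11 and HOPX the lowest at -1.10.

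Genes of the type I interferon response were lower in PG1hi. Of 30 tested members 28 had a log2 change below 0, with a median of -0.22 in the paired fit, and the median was -0.25, -0.21 and -0.19 in tumors 1, 2 and 3. In the paired fit 16 fell and 0 rose, or 21 adjusted over the list alone. MX2, an antiviral GTPase, fell by 0.51 ± 0.07 (SE), from 59.5 ± 12.5 to 41.5 ± 6.3 CPM (SD, n = 3), IFI44L by 0.43 ± 0.06, the oligoadenylate synthetase gene OAS1 by 0.28 ± 0.05 and IFI6 by 0.25 ± 0.04. MHC class I genes fell in 6 of 15 cases and rose in 0, or 9 adjusted over the list alone. B2M, the light chain of the MHC class I molecule, went from 7217 ± 279 to 6268 ± 256 CPM and fell by 0.20 ± 0.03. The peptide transporter gene TAP2 fell by 0.38 and HLA-B by 0.16. Against the other genes, camera gave adjusted p = 3.58e-11 for the interferon list and 0.000406 for the MHC class I list without the block. With an estimated correlation both had adjusted p = 0.283. LYZ, a macrophage marker that epithelial cells also express, was lower in PG1hi too, at 23.1 ± 0.4 against 29.3 ± 1.6 CPM (SD, n = 3). The 20 listed macrophage markers had a median of 0.06 CPM in PG1lo (scaled by library size alone). Macrophages of the host would be mouse cells, so this level does not show whether they were present.

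Epithelial genes and lysosomal genes were lower in PG1hi as well. Among 25 epithelial genes 7 fell and 0 rose in the paired fit, or 14 passed adjusted over the list alone, 1 of them higher. The intestinal keratin gene KRT20 fell by 0.36 ± 0.05 (SE), the claudin gene CLDN4 by 0.23 and KRT19 by 0.16, while CDH1 had a log2 change of -0.07 and did not pass (edgeR with block, adjusted p = 0.499). Among 30 lysosomal genes 5 fell and 0 rose, or 7 adjusted over the list alone. The cathepsin genes CTSD and CTSB fell by 0.26 and 0.25, and the acid ceramidase gene ASAH1 fell by 0.30. Camera without the block gave adjusted p = 0.00155 for both lists. With an estimated correlation it gave adjusted p = 0.284 for the epithelial and 0.443 for the lysosomal list. The interferon, MHC class I, epithelial and lysosomal lists kept their calls when any single library or tumor was left out.

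Genes of mitosis and of DNA replication were lower in PG1hi in tumors 2 and 3 and not in tumor 1. The median change of 30 mitotic genes was 0.04, -0.30 and -0.14 in tumors 1, 2 and 3. The median of 26 replication genes was 0.12, -0.36 and -0.23. In the paired fit 3 mitotic genes fell and 0 rose, or 8 adjusted over the list alone. They were CDK1 at -0.42 ± 0.08 (SE), TOP2A at -0.27 ± 0.06 and UBE2C at -0.33 ± 0.08, while MKI67 had a change of 0.04 and did not pass. Without tumor 2, UBE2C had a paired change of -0.20 (edgeR, adjusted p = 0.164). Of the replication genes 3 fell and 0 rose, or 4 adjusted over the list alone, with RRM2 at -0.34, CDC6 at -0.34 and TYMS at -0.42. Camera without the block gave adjusted p = 0.000275 and 0.000523, and 0.7 and 0.712 with an estimated correlation. Without PG1hi replicate 2 the mitotic list had adjusted p = 0.584, and without PG1hi replicate 3 the replication list had 0.23. Among 20 NF-kB targets and cytokines 3 fell, the chemokine genes CXCL8 and CXCL1 (by 0.76 and 0.72) and ICAM1, and 0 rose, also 3 adjusted over the list alone. That list had 8 members above 0 and 12 below, with a paired median of -0.06. Its medians were -0.08, -0.03 and 0.002 in tumors 1, 2 and 3. Camera without the block gave adjusted p = 0.00155 for it, 0.443 with an estimated correlation and 0.102 without PG1hi replicate 1.

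Ribosomal protein genes were slightly higher in PG1hi. Of 64 members 62 had a log2 change above 0, with a median of 0.10, and 3 passed in the paired fit, or 13 adjusted over the list alone. RPS19 rose by 0.22 ± 0.04 (SE), RPL14 by 0.20 and RPL7 by 0.17. The median was 0.16, 0.03 and 0.11 in tumors 1, 2 and 3. Camera without the block gave adjusted p = 1.97e-06, and 0.724 with an estimated correlation. When PG1lo replicate 1 was left out, its adjusted p was 0.109. The share of ribosomal RNA genes was higher in PG1hi in the same tumors. Nuclear-encoded oxidative phosphorylation genes had 40 of 49 members above 0 and fatty acid oxidation genes 18 of 24, but 0 members of either list passed in either edgeR fit and 0 adjusted over the list alone. The medians in tumors 1, 2 and 3 were 0.11, -0.02 and 0.02 for the first list and 0.17, 0.02 and 0.01 for the second. Their camera adjusted p without the block was 0.0358 and 0.0275, and 0.778 and 0.7 with an estimated correlation. The call of the first list was lost without PG1hi replicate 1 (adjusted p = 0.189), PG1hi replicate 3 (0.14) or PG1lo replicate 1 (0.497), and that of the second without PG1hi replicate 1 (0.33), PG1hi replicate 3 (0.0517) or PG1lo replicate 2 (0.106), by camera.

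Genes of Wnt signaling, of the ATF4 stress response and of mesenchymal transition were higher in PG1hi as lists, the last mainly in tumor 2. Among 14 Wnt targets NKD1 and TNFRSF19 rose, by 0.83 and 0.56, and CCND1, cyclin D1, fell by 0.20, or 7 passed adjusted over the list alone, 6 of them higher. Among 22 ATF4 targets 3 rose, or 7 adjusted over the list alone: ASNS, asparagine synthetase, by 0.38, PSAT1, an enzyme of serine synthesis, by 0.34 and the amino acid transporter gene SLC3A2 by 0.19. Of 18 mesenchymal genes TWIST1, TNC, TGFBI and FN1, fibronectin, rose, the last pair by 0.49 and 0.25, while the integrin gene ITGB6 fell by 0.40 and VIM, vimentin, had a change of 0.34 that did not pass. Adjusted over the list alone 6 passed, 4 of them higher. The mesenchymal list had 10 members above 0 and 8 below, with medians of 0.04, 0.23 and 0.01 in tumors 1, 2 and 3. In the same tumors the medians were 0.17, 0.06 and 0.11 for Wnt targets and 0.11, 0.14 and 0.08 for ATF4 targets. Among 9 fibroblast markers 2 also rose in the paired fit, COL5A1 (by 0.52) and COL1A2, and 0 fell, with a list median of 0.16 (camera without block, adjusted p = 0.28). Camera without the block gave adjusted p = 0.000151, 0.00202 and 0.00743 for the Wnt, ATF4 and mesenchymal lists, each 0.283 with an estimated correlation. Without PG1hi replicate 1 the mesenchymal list had adjusted p = 0.0514 and without PG1lo replicate 2 it had 0.066.

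**Figure D2:**
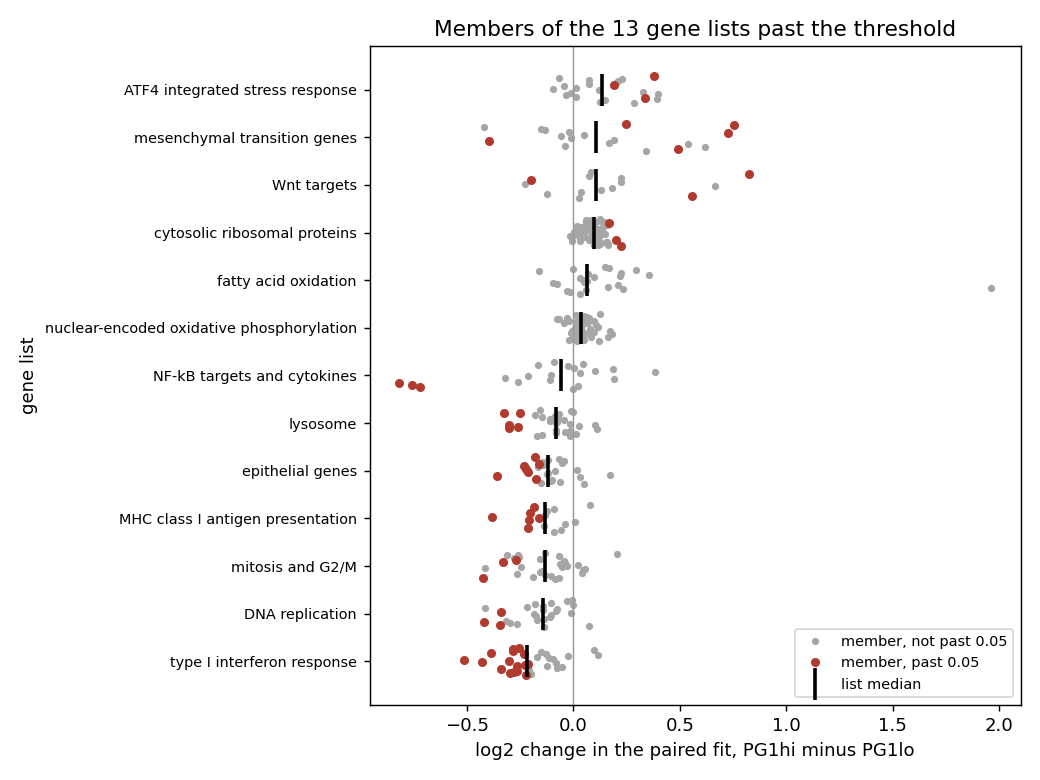
Points show the log2 change of PG1hi minus PG1lo in the paired fit for each tested member of 13 lists. These lists passed the camera threshold without the block. Members past an adjusted p of 0.05 in the paired fit are red, and a vertical mark shows the list median. The interferon list has the lowest median at -0.22 and the ATF4 list the highest at 0.14.

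Few NRF2 targets and antioxidant enzymes differed. Of 25 NRF2 targets 1 passed in the paired fit, the ferritin light chain gene FTL, which rose by 0.31 ± 0.04 (SE) (5 adjusted over the list alone). NQO1 and HMOX1 had log2 changes of 0.10 and -0.21, and neither passed. Of 22 antioxidant enzymes 0 passed in either edgeR fit, also 0 adjusted over the list alone. CAT, catalase, was at 38.9 ± 4.9 CPM in PG1hi and 37.5 ± 4.7 in PG1lo (SD, n = 3 each), and GPX2 had a change of 0.11. Of 18 oxidases that make superoxide or peroxide, 2 rose and 1 fell in the paired fit (5 adjusted over the list alone). Of all 15077 tested genes 767 passed in that fit. Among 22 hypoxia genes CA9 rose and INSIG2 fell by 0.27 (3 adjusted over the list alone). Camera without the block gave adjusted p = 0.483 for NRF2 targets, 0.724 for antioxidant enzymes, 0.796 for oxidases and 0.826 for hypoxia genes. Without PG1hi replicate 1 the hypoxia list was called, with adjusted p = 0.00271.

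In the paired fit 4 more lists passed. Glycolysis genes were lower (adjusted p = 0.0314, camera with block; 0.497 with an estimated correlation), with 3 of 21 falling: the glucose transporter genes SLC2A3 by 0.47 and SLC2A1 by 0.19, and the lactate transporter gene SLC16A3 by 0.27. YAP and TEAD targets were lower (adjusted p = 0.00454; 0.463 with an estimated correlation), with F3, tissue factor, falling by 0.71, CCN2 by 0.49, AMOTL2 by 0.41 and CCN1 by 0.34, and TGFB2 rising by 0.53 among 18. Endocytosis genes were lower (adjusted p = 0.0349; 0.601 with an estimated correlation), with 3 of 26 falling, CLTB by 0.24. TGF-beta targets were higher (adjusted p = 0.0491; 0.56 with an estimated correlation; tumor medians -0.02, 0.12 and 0.09 in tumors 1, 2 and 3), with BAMBI and TGFBI rising and PMEPA1 falling by 0.21 among 18. Adjusted over the list alone 4, 5, 6 and 3 members of these lists passed.

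Intestinal genes moved both ways, as 4 of 15 rose and 3 fell in the paired fit (7 adjusted over the list alone). VIL1 and HNF4A, a transcription factor of gut and liver epithelium, rose by 0.88 and 0.47, while CEACAM6 and CEACAM5 fell by 0.52 and 0.58. The gastric genes PSCA and AQP5 fell by 0.47 and 0.20 among 7 (3 adjusted over the list alone). ERBB2 was at 12633 ± 722 CPM in PG1hi and 12822 ± 1153 in PG1lo (SD, n = 3 each). Its neighbors PPP1R1B and PNMT rose by 0.53 and 0.77, while TGFA, a ligand of the EGF receptor, fell by 0.34, in a list with 2 of 20 rising and 2 falling (4 adjusted over the list alone). The metallothionein gene MT2A rose by 0.56, 1 of 4 tested (3 adjusted over the list alone). In the stem cell list CD24 fell by 0.36 and TNFRSF19 rose among 15 (3 adjusted over the list alone).

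Stress and lipid lists showed scattered members. Among 22 immediate early genes ATF3 and NR4A2 fell by 0.24 and 0.23 and KLF2 rose by 0.23 (3 adjusted over the list alone). DNAJB1 fell by 0.16 among 15 heat shock genes (1 adjusted over the list alone) and GDF15 rose by 0.27 among 20 p53 targets (2 adjusted over the list alone). Of 20 unfolded protein response genes 0 passed in either edgeR fit, also 0 adjusted over the list alone. SREBF1 and ACSS2 fell by 0.22 and 0.32 among 17 fatty acid synthesis genes (4 adjusted over the list alone). Of 24 cholesterol synthesis genes 1 rose and 1 fell in the paired fit (3 adjusted over the list alone), and 17 had a change below 0. None of the lists in these last 2 paragraphs passed camera in either fit, and the metallothionein list was too short to test.

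Markers of other cell types were mostly near the detection limit. Cells of the host would be mouse cells, and the counts are on human genes. Low levels therefore do not show how many host cells the fractions held. COL5A1 rose by 0.52, from 23.4 ± 4.7 to 33.5 ± 4.7 CPM (SD, n = 3), and COL1A2 was at 0.833 ± 0.79 against 0.171 ± 0.19 CPM, among 9 fibroblast markers (3 adjusted over the list alone). LYZ fell by 0.34 among 5 macrophage markers (2 adjusted over the list alone), and LCN2, which epithelial cells also make, fell by 0.63 among 4 neutrophil markers (1 adjusted over the list alone). CD79A and PRF1 rose by 1.91 and 0.79, both of the 2 tested lymphocyte markers, at 2.64 ± 0.99 and 4.99 ± 0.69 CPM in PG1hi (2 adjusted over the list alone). Of 7 smooth muscle, 7 endothelial, 2 red blood cell and 3 adipocyte markers 0 passed in either edgeR fit, also 0 adjusted over each list alone. Camera called none of the 4 of these lists long enough to test, with adjusted p = 0.056 for macrophages without the block; without PG1hi replicate 3 (adjusted p = 0.0466) or PG1lo replicate 1 (0.0173) that list was called, as lower in PG1hi.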

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

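The share of counts in rows that name no gene stood out as a signal outside the comparison. These rows held 3.79% ± 0.80 of the counts in PG1hi and 3.13% ± 0.60 in PG1lo (SD, n = 3 each), and PG1hi was higher in 3 of 3 tumors (two-sided exact permutation test, p = 0.3, where 0.1 is the smallest possible). The largest single such row held 2.71% in PG1hi and 2.14% in PG1lo. What these rows are was not analysed here. Groups of 3 are too small for a test of outlying libraries.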

How the results depend on the processing

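The comparison without block rests on few genes and moved with most settings, and the fits with the authors' scaled values and the variations of the paired fit, though not the block itself, were chosen after the data were seen. Without block, 3 genes passed (1 higher, 2 lower in PG1hi). The replicate block gave 767 (249 higher, 518 lower), DESeq2 118 (38 and 80) and no low-count filter 27 (10 and 17). Upper-quartile factors gave 5 (4 lower), limma-voom 2 (1 lower), library size alone 1 (0 lower) and the authors' scaled values with limma 1 (0 lower). Against a 1.5-fold change edgeR called 0 (0 higher, 0 lower), where 1141 genes had an unadjusted p under 0.05 in the plain test. Leaving out 1 library or 1 tumor gave 0 to 2 genes, 0 to 2 higher and 0 to 2 lower. TGM2 and CYP4B1 missed the threshold without any 1 library, and NKD1 (adjusted p 0.0305 to 0.104 over the 6 libraries) missed it without PG1hi replicate 2 (adjusted p = 0.104), PG1lo replicate 1 (0.0764) or PG1lo replicate 2 (0.096) in edgeR; fewer libraries were left in each. Other causes were not tested. In the paired fit, 767 became 500 (160 higher, 340 lower) with the authors' scaled values, 498 of them shared with the paired calls, and 4 (1 and 3) against a 1.5-fold change. No filter gave 412 higher. Leaving out 1 tumor gave 522 to 1017 genes, 179 to 408 higher (408 without tumor 1) and 343 to 642 lower (343 without tumor 3). With the other paired settings the count ranged from 616 to 1101. Of 35 lists 13 passed; with an estimated correlation 0 passed and with fry 0, and in the paired fit 17, 0 and 6. The block kept all 13 calls and added 4. Of the 13 lists, 6 kept their call in all 9 fits without 1 library or 1 tumor: interferon, MHC class I, ATF4, epithelial, Wnt and lysosome. The highest adjusted p over these fits was 0.594 for mitosis, 0.286 for DNA replication, 0.795 for oxidative phosphorylation, 0.414 for fatty acid oxidation, 0.109 for ribosomal proteins, 0.102 for NF-kB targets and 0.069 for mesenchymal genes (camera). ERBB2 had a log2 change of 0.0149 with library size alone, against -0.0214. Across the left-out libraries and tumors it ranged from -0.083 to 0.0478, CAT from -0.0442 to 0.15, MKI67 from -0.0793 to 0.214 and CDH1 from -0.208 to 0.0667, so that their signs turned; none was called. Also without the block, CA9 ranged from 0.224 to 1.80, VIM from 0.0699 to 0.673, HMOX1 from -0.404 to -0.0166, NQO1 from 0.0388 to 0.172 and GPX2 from 0.0612 to 0.155, with no turn. In the paired fit CA9 ranged from 0.855 to 1.11 without 1 tumor. Of 96 named genes called in the paired fit, 28 moved by over 1.5 times in the fit without block when 1 library was left out, and 0 turned. In the paired fit 72 of the 96 were also called without each tumor in turn, NKD1, TGM2, CYP4B1 and CA9 among them. There 1 gene, UBE2C, moved by over 1.5 times, from -0.33 to -0.20 without tumor 2. COL1A2 was not among the genes tested without tumor 3. Among 23 lists followed through the alternatives, leaving out libraries or tumors also turned the direction of 4 that were not called with all 6 libraries; over these fits the adjusted p ranged from 0.35 to 0.846 for antioxidant enzymes, 0.369 to 0.933 for oxidases, 0.105 to 0.948 for fibroblast markers and 0.00271 to 0.923 for hypoxia genes. The block turned 3 others of the 35, intestinal, stem cell and endothelial genes, with 0 called in either fit. Causes of these turns were not tested.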

Other observations

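The tests of the macrophage genes and of the ribosomal RNA share, the offsets for GC content and length, and the list of squamous differentiation genes were chosen only after the results of the comparison were seen. Bootstrap values below resample the genes of a list and do not measure the spread between tumors. Many genes of this list of stratified squamous epithelium were lower in PG1hi, with a median paired log2 change of -0.24. IVL, involucrin, a protein of the cornified envelope, fell from 420 ± 139 to 235 ± 56.3 CPM (SD, n = 3), and the protease inhibitor gene A2ML1 from 1034 ± 295 to 673 ± 162 CPM. SPRR3 fell by 0.70 ± 0.06 (SE), SCEL by 0.61 ± 0.05, KRT5 by 0.65 ± 0.06 and GRHL3, a transcription factor of the epidermal barrier, by 0.59 ± 0.07 in the paired edgeR fit. Of 41 tested members 19 fell and 1, ECM1, rose, by 0.42 ± 0.05. These genes were singled out after their values were seen.

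A candidate explanation is that the lower level in PG1hi extends to members of the programme beyond the genes first noticed. Among the 31 members not looked at before, the median log2 change was -0.21 (bootstrap SE 0.0469), and -0.20, -0.12 and -0.12 in tumors 1, 2 and 3. Of these members 23 were below 0 and 8 above, and 9 fell and 1 rose in the paired fit. Those that fell included the related keratin genes KRT6A, KRT6B and KRT6C, whose estimated counts may not be separate. Those above 0 included FLG, SPRR1A, SPRR1B and KRT10, at 0.0002, 0.16, 0.14 and 0.01, which did not pass. Not every member was lower, so the list does not show a fall of squamous differentiation as a whole. KRT17, whose counts had been looked at in another check, was left out of the 31 after a first run of the test. The paired camera test of these 31 gave p = 8.33e-06, and p = 0.0366 with an estimated correlation. The 31 come from the same libraries and from a list written after related genes stood out, so this test is not independent support. A trend with GC content and transcript length was argued against: with offsets for both in the paired fit, the median of all 41 was -0.26 (bootstrap SE 0.0581). What else differs between the fractions stays open, and a biological difference by PG1 fluorescence may underlie it as a hypothesis.

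The lower interferon list was set against a GC and length trend and against macrophage RNA counted on human genes in PG1lo. With the offsets the list median was -0.20 (bootstrap SE 0.0247), where it was -0.22 before, and 19 of 30 members passed. Whether macrophage RNA was a source could not be decided from the marker levels. The 20 listed macrophage markers had a median of 0.06106 CPM in PG1lo, scaled by library size alone, with a bootstrap upper limit of 0.1674. Of them 14 were under 0.1 CPM, where the median difference of the interferon members was 15.15 CPM. This measure replaced earlier ones after the values were seen, so it carries less weight: first the highest of 5 markers, LYZ not among them, then the highest of all 20, which decided nothing at 28.96 CPM for LYZ, a gene that epithelial cells also express. Macrophages of the host would be mouse cells, and how far single mouse genes are counted on human ones was not tested. Low marker levels could therefore arise with or without macrophages, and they set no limit on mouse reads counted on interferon genes. A difference in interferon signaling between cells of high and low PG1 fluorescence stays open and untested.

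The higher ribosomal protein list kept a median of 0.0985 (bootstrap SE over genes 0.00482) with the GC and length offsets, against 0.0964 before, which argues against that trend as the cause. The spread between tumors was wider, with medians before the offsets of 0.16, 0.03 and 0.11 in tumors 1, 2 and 3. A difference in RNA quality or ribosomal RNA carry-over cannot be told apart from the fractions, because the ribosomal RNA share was higher in PG1hi in 3 of 3 tumors (exact permutation p = 0.3) and 3 tumors are too few to relate the 2 shares.

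Without block, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes as the real one, namely the real one with 3, and the highest of the others gave 2. With the block, 4 splits part all 3 tumors: the real one gave 767 and the highest of the other 3 gave 0; those exchange the fractions of 1 tumor. In both cases the splits are too few for a share under 0.05.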
